A study of Sus scrofa with 48 samples.

How the data were processed

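Bulk RNA sequencing of liver from neonatal pigs (Sus scrofa) was analysed from 48 libraries in 6 groups. Per the labels' protocols, RNA was extracted from shock-frozen liver, 1000 ng of RNA entered an mRNA library kit, 150 bp read pairs were sequenced on a NovaSeq instrument, and adapters were trimmed with TrimGalore. The submitters' processing notes name HTSeq, DESeq2 and the pig genome build Sscrofa11.1 without versions or roles. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. The table the authors deposited holds raw counts of reads per gene, with whole numbers that sum to a different total in each library.

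The table had 35460 entries. Of these, 3552 carried no gene name and held between 0.2% and 0.4% of the counts of a library, and these stayed out of library sizes and tests. 1 further entry was empty, which left 31907 named genes. In 15410 of them the file gave only an Ensembl identifier, of which 851 received a symbol from an Ensembl name table, 731 from a RefSeq table, and 13828 kept the identifier. In 638 entries the symbol in the file differed from the NCBI symbol of the same gene identifier. The entry named HPS5 carries the NCBI gene identifier of SAA3, a serum amyloid A gene, and is written SAA3 (listed as HPS5) below. ENSSSCG00000013369, which the file describes as serum amyloid A2, was read as SAA2. These readings, and 4 others of the same kind for list members, were made from identifiers after the table was opened. Reads of near-identical family members can be shared between genes, so values for serum amyloid A, metallothionein, sulfotransferase, glutathione transferase, cytochrome P450 and histone genes are uncertain.

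Total counts per library ranged from 12.3 to 18.7 M (median 14.9, M for 1e+06 counts). Floors and intervals computed from counts cover counting error alone. The labels do not say that libraries came from separate animals, and they give no litter, sex or pathogen, so the p-values measure the spread between these samples. XIST and Y-linked genes were left out of the named genes. Groups and replicate numbers came from the sample titles.

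Differential expression was tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM normalization, the filterByExpr filter by group, and robust estimation. One mean was fitted per group over all 48 libraries, so that groups of 2 and 4 libraries shared the estimate of spread. The filter kept 15274 genes, the common dispersion was 0.232, and the fit had 42 residual degrees of freedom. P-values were adjusted over all tested genes within a comparison by the Benjamini-Hochberg method with a threshold of 0.05, and each adjusted p below comes from this test unless another tool is named. Levels are given as CPM on TMM-normalized library sizes (mean ± SD over libraries) unless stated. The standard error (SE) beside a log2 fold change is its absolute value divided by the square root of the F statistic. It therefore restates that test and is no separate measure of spread. Scores of a gene list are the mean over its members of log2 CPM (prior count 2) centred on the mean of all libraries. Intervals of score differences come from a linear model over the 38 infected libraries, with the regimen as factor, and are not adjusted over lists, where chance gives about 1 in 20.

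Before the data were examined, the comparisons, their tests, 29 gene lists, the cell type marker sets and most of the alternative settings were fixed. Lists were tested with camera (limma 3.58.1) against all other genes, with the correlation between members estimated from the data, and adjusted over the 39 lists and marker sets with at least 4 tested members. Camera with a preset correlation of 0.01 and fry were alternatives. The named genes followed a rule: in 4 main comparisons the 10 largest rises and 10 largest falls among genes past the threshold with a symbol and a mean of at least 2 CPM, 3 of each elsewhere, up to 4 members of each list with the smallest p, and 20 preset genes of inflammation and fuel metabolism. Some of the genes this rule gave are not reported here. After the values were seen, fitted fold changes were restricted to genes past the threshold, and preset genes that did not pass are given as CPM. Single members that moved against their list (CD14 and INSIG1 with infection, GLUD1 and CTH in RG minus control) lie outside the rule and were named after their values were seen; they were not refitted with libraries left out. Genes with a group of all 0 counts are given as bounds against a floor of 3 counts over the group.

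The alternatives were RLE normalization, no filter, DESeq2 1.42.0, limma-voom with quality weights, fits of the compared groups alone, the replicate number as a block, a 3 degree of freedom spline of library number, 9 surrogate variables (sva 3.50.0), a test against a fold change of 1.5, and each library left out. Estimation without the robust option and fits without 4 libraries that stood apart (infected control replicates 7 and 10, uninfected BHB replicate 1 and uninfected RG replicate 1) were added after the data were seen, as were CPM means and score intervals without 1 library.

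The pipeline was tested on simulated counts with 200 changed genes, in 3 runs per comparison. For infection averaged over regimens, 67.2% of genes changed 2-fold and 92.9% of genes changed 4-fold were recovered over 14959 genes. For RG minus control in infected libraries the shares were 66.7% and 93.9% over 14942 genes, and for infection under the control regimen, with 2 uninfected libraries, they were 11.4% and 63.6% over 14945 genes. For RG minus control in uninfected libraries, 7.46% of the 2-fold and 50% of the 4-fold changes were recovered over 14919 genes, and for BHB minus RG in uninfected libraries 14.9% and 68.7% over 14960 genes. Between 1.7% and 5.4% of the calls in these runs were false. The simulated genes were independent and held no structure between libraries, so these shares need not hold in the real libraries.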

Results

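Liver RNA from neonatal pigs was sequenced in 48 libraries to ask how infection and the supply of glucose or a ketone body changed hepatic transcripts. The control regimen held 10% glucose, the BHB regimen 2.5% glucose with 2.5% of the ketone body beta-hydroxybutyrate, and the restricted glucose regimen (RG) 2.5% glucose. Infected livers gave 13 control, 13 BHB and 12 RG libraries, and uninfected livers gave 2, 4 and 4. Mean total counts were 15.86 ± 2.17 M (SD, M for 1e+06 counts) in infected control, 14.91 ± 1.58 in infected BHB and 15.47 ± 1.83 in infected RG libraries. The uninfected libraries held 15.54 ± 1.67 (control), 14.54 ± 1.92 (BHB) and 13.59 ± 1.64 M (RG). Mitochondrial transcripts took 34.3% of the counts of infected control replicate 7 and 16.81% of uninfected RG replicate 1, against group means between 5.64% and 8.84%. The first 3 principal components held 21.3%, 14.4% and 8.5% of the variance.

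To identify which transcripts differed between infected and uninfected liver, the infection effect was averaged over the 3 regimens. Infection led to an increase in the interferon-induced chemokine CXCL11 by 84-fold, in the antiviral gene OASL by 44.4-fold, in ISG15 by 29.9-fold and in the exonuclease ISG20 by 23.1-fold. The serum amyloid A genes SAA2 and SAA3 (listed as HPS5), acute phase reactants, increased by 13.7-fold and 9.8-fold. Albumin (ALB), the main secreted protein of hepatocytes, was 5.5-fold lower, and CYP7A1, the rate-limiting enzyme of bile acid synthesis, was 31.6-fold lower. Group means of CYP7A1 were 0.118 to 0.276 CPM with and 4.07 to 6.42 CPM without infection, so the size of its fall is uncertain. Mean ALB was 11500 ± 1710 CPM (SD, n = 2) without and 2640 ± 1510 CPM (n = 13) with infection under the control regimen, and 27200 ± 4980 (n = 4) and 4330 ± 2400 CPM (n = 12) under RG. Across 15274 tested genes, 2159 were higher and 2014 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted). Of these 4173 genes, 4095 (98.1%) had the same fitted direction under each of the 3 regimens. The genes were chosen by the mean of these same 3 effects, which favours agreement, so this share is no separate test. Without uninfected control replicate 1 the count was 2452 genes, 1089 higher and 1363 lower. With the replicate number as a block 4051 genes passed, 2647 of them among the 4173, and with surrogate variables 4994, of which 3315 were among them.

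Among the largest rises, log2 fold changes (± SE) were 6.39 ± 0.91 for CXCL11 (edgeR adjusted p = 6.53e-07, 38 of 38 infected libraries above the uninfected mean of their regimen), 5.47 ± 0.69 for OASL, 4.90 ± 0.83 for ISG15 and 4.84 ± 0.88 for PPP4R4. RSAD2 (4.69 ± 0.98), MUC13 (4.63 ± 1) and ISG20 (4.53 ± 0.47) followed, and the highest edgeR adjusted p of these 7 genes was 0.000432. LY6H and H2AC20 also rose but had no count in 1 uninfected group each. LY6H was at least 65.8-fold higher in infected than in uninfected BHB libraries, and H2AC20, a histone gene with near-identical copies, at least 38.3-fold higher in infected than in uninfected control libraries. Among the largest falls were the glutathione transferase GSTA1 (-3.44 ± 0.43), HSD17B6 (-3.31 ± 0.31), AADAC (-3.23 ± 0.55), UPB1 (-3.12 ± 0.37), SLC7A8 (-3.12 ± 0.40) and CX3CR1 (-3.11 ± 0.65). NGFR (-3.10 ± 0.26), CRABP1 (-3.04 ± 0.33) and RIMS2 (-3.03 ± 0.41) followed, with an edgeR adjusted p of at most 0.000297 for these 9 genes, each lower in at least 37 of 38 infected libraries. Mean log2 CPM of ALB was 11.19 ± 0.71 in infected control, 11.49 ± 0.67 in infected BHB and 11.91 ± 0.68 in infected RG libraries, against 13.48 ± 0.22, 14.21 ± 0.29 and 14.71 ± 0.27 without infection.

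**Figure D1:**
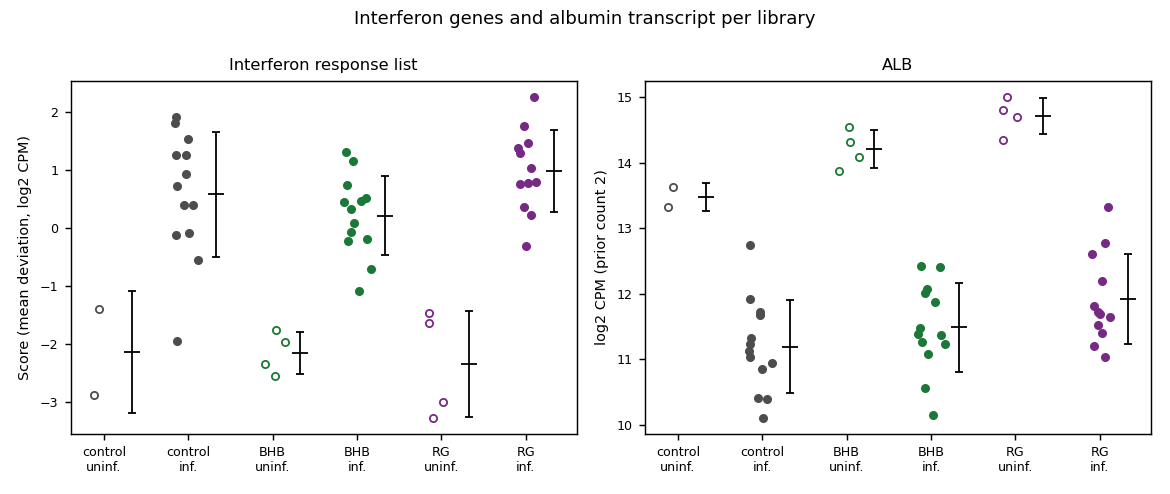
Interferon response list score (mean centred log2 CPM of 34 genes) and ALB log2 CPM in each library by group, with open circles for uninfected libraries, filled circles for infected libraries and black bars for mean ± SD. Infected control replicate 10 had an interferon score of -1.942, inside the uninfected range of -3.273 to -1.399, while the other 12 infected control libraries lay between -0.55 and 1.925.

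To describe the immune response by group, the lists of inflammatory genes were counted. In the interferon response list 32 of 34 genes rose and 0 fell (32 and 0 adjusted over the list alone), with a median log2 fold change of 2.80 and examples CXCL9 (4.09 ± 0.44), IDO1 (3.69 ± 0.41) and PSMB8 (2.66 ± 0.34). Acute phase proteins gave 12 rises and 1 fall of 20 (12 and 1 adjusted over the list alone, median 0.82), with LCN2 at 1.79 ± 0.26, ITIH4 at 1.42 ± 0.21 and haptoglobin (HP) at 0.97 ± 0.19, while CD14 fell. Of 11 negative acute phase proteins, which include ALB, 6 fell (6 over the list alone, median -0.70), as RBP4 (-0.95 ± 0.18) and transferrin (TF, -1.11 ± 0.22) did. Complement genes went both ways, with 3 rises and 4 falls of 18 (3 and 4 over the list alone, median -0.12), including C2 (1.74 ± 0.26) and MASP1 (-1.98 ± 0.20). Coagulation genes gave 7 falls of 17 (9 over the list alone, median -0.44), with KLKB1 at -1.65 ± 0.20 and SERPIND1 at -1.56 ± 0.22. Uninfected BHB replicate 2 and uninfected RG replicate 3 had cytokine list scores of 2.915 and 2.867, against at most 0.309 in the other 8 uninfected libraries. These raise the uninfected means, and no fit left both out, so the next counts cannot show that cytokine genes stayed unchanged. Of 32 cytokine and NF-kB genes 4 rose and 1 fell (1 and 0 adjusted over the list alone, median 0.03). Among these, the edgeR adjusted p of CCL5 (2.44 ± 0.68) was 0.054 without uninfected control replicate 1 and 0.062 without replicate 2, and that of SOD2 (1.45 ± 0.48) was 0.13 and 0.0784, while with the replicate number as a block they were 0.226 and 0.338. With an estimated correlation between members, camera gave adjusted p = 0.0818 for interferon, 0.0858 for acute phase, 0.168 for negative acute phase, 0.619 for complement, 0.145 for coagulation and 0.591 for cytokine genes. The interferon list passed without uninfected control replicate 1 (camera adjusted p = 0.0205), without uninfected RG replicate 3 (0.0491) and without infected control replicate 10 (0.0349). Acute phase proteins also passed without uninfected RG replicate 3 (camera adjusted p = 0.0491).

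To describe fuel metabolism under infection, the metabolic lists were counted in the same way. Glycolysis genes gave 13 rises and 0 falls of 20 (13 and 0 adjusted over the list alone, median 0.64), led by hexokinase 2 (HK2, 2.22 ± 0.41) and LDHA (2.07 ± 0.44). With the replicate number as a block, LDHA and the glucose transporter SLC2A3 of this list did not pass (edgeR adjusted p = 0.125 and 0.0996). Mitochondrial fatty acid oxidation gave 12 falls of 19 (12 over the list alone, median -0.47), with DECR1 at -1.49 ± 0.19 and ACAA2 at -1.80 ± 0.24. In bile acid metabolism 10 of 18 genes fell (10, and 1 rise, over the list alone, median -0.79), among them CYP7A1 (-4.98 ± 0.56) and the uptake transporter SLCO1B3 (-2.20 ± 0.23). Cholesterol synthesis had 13 falls and 1 rise of 24 (15 and 1 over the list alone, median -0.58), with MVK at -1.05 ± 0.20 and the rise in INSIG1, which restrains sterol synthesis. Among glucose-responsive hepatic genes 7 of 14 fell and 1 rose (7 and 1 over the list alone, median -0.60), with pyruvate kinase (PKLR) at -2.13 ± 0.38. PPARA targets had 7 falls and 1 rise of 16 (8 and 1 over the list alone, median -0.73), such as VNN1 (-2.63 ± 0.31). For gluconeogenesis 5 of 12 genes fell (6, and 1 rise, over the list alone, median -0.44), including FBP1 (-1.24 ± 0.27). Glycogen genes fell in 5 and rose in 1 of 12 cases (7 and 1 over the list alone, median -0.85), and lipogenesis genes in 9 and 1 of 17 (9 and 1, median -0.42), with DGAT2 at -2.89 ± 0.32. Ketone body genes had 4 falls and 1 rise of 10 (5 and 1 over the list alone), with a median of -0.65 over the members with counts in every group. BDH1, which interconverts the 2 ketone bodies, stood at -1.70 ± 0.36. None of these lists passed camera, with adjusted p = 0.178 (glycolysis), 0.0987 (fatty acid oxidation), 0.107 (bile acids), 0.178 (cholesterol), 0.0987 (glucose-responsive), 0.0987 (PPARA), 0.178 (gluconeogenesis), 0.102 (glycogen), 0.381 (lipogenesis) and 0.243 (ketone bodies) with an estimated correlation.

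Amino acid and stress lists followed. Urea cycle and amino acid catabolism had 6 falls and 2 rises of 17 (7 and 2 adjusted over the list alone, median -0.30), with OTC at -2.54 ± 0.37, while ATF4 targets had 8 rises and 4 falls of 21 (10 and 5, median 0.43), such as NUPR1 (2.52 ± 0.48) and PSAT1 (-2.06 ± 0.27). ER stress chaperones rose in 10 of 15 cases (10 over the list alone, median 0.70), with MANF at 1.28 ± 0.23. Of 12 hypoxia genes 7 rose (7 over the list alone, median 0.50), among them NDRG1 (1.32 ± 0.40). Without uninfected control replicate 1 the edgeR adjusted p of NDRG1, KDM3A, ANKRD37 and HIF1A was 0.065, 0.0712, 0.101 and 0.115, and without replicate 2 that of NDRG1, ANKRD37 and HIF1A was 0.0736, 0.0781 and 0.0511. With the replicate number as a block, these 4 genes had log2 fold changes of 0.26, 0.07, 0.91 and 0.30 and did not pass (edgeR adjusted p = 0.601, 0.844, 0.168 and 0.261). Glucocorticoid targets gave 5 rises and 1 fall of 10 (5 and 1, median 0.58), with FKBP5 at 0.76 ± 0.16, and xenobiotic metabolism 5 falls of 15 (5, median -0.33), with FMO5 at -2.53 ± 0.30. In the antioxidant list 2 rose and 4 fell of 10 (2 and 4), and its median was 0.05 while its mean was -0.05 and camera's direction was down. The insulin and growth list had 2 rises and 3 falls of 11 (2 and 3, median -0.14), the pentose phosphate list 1 fall of 8 (1, median 0.21) and the TCA cycle list 1 rise and 4 falls of 22 (1 and 4, median -0.11). Nuclear oxidative phosphorylation had 0 rises and 0 falls of 42 (0 and 0, median -0.03), mitochondrially encoded genes 1 fall of 13 (0, median -0.23) and proliferation 1 fall of 17 (0, median -0.17). With an estimated correlation, camera adjusted p was 0.304 (urea cycle), 0.529 (ATF4), 0.304 (chaperones), 0.381 (hypoxia), 0.179 (glucocorticoid), 0.107 (xenobiotic), 0.839 (antioxidant), 0.607 (insulin), 0.607 (pentose phosphate), 0.65 (TCA cycle), 0.933 (oxidative phosphorylation), 0.719 (mitochondrially encoded) and 0.726 (proliferation).

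Markers of liver cell types were examined beside these lists. Hepatocyte markers had 6 falls of 12 (7 adjusted over the list alone, median -0.51), with ASGR1 at -1.37 ± 0.20. Endothelial markers had 5 falls of 12 (7, median -0.55), with the sinusoidal genes CLEC4G at -2.48 ± 0.26 and STAB2 at -1.58 ± 0.23. Monocyte and macrophage markers had 6 falls and 1 rise of 15 (8 and 1, median -0.35), with MSR1 at -1.55 ± 0.27, and neutrophil markers 5 rises of 13 (5, and 1 fall, median 0.49), with CSF3R at 1.88 ± 0.32. In T and NK cell markers 2 of 14 rose and 1 fell (2 and 1, median 0.57), with CD8B at 3.10 ± 0.55, and stellate and fibroblast markers gave 2 rises and 3 falls of 12 (2 and 4, median -0.33). Cholangiocyte markers gave 1 rise and 1 fall of 8 (1 and 1, median 0.10), B and plasma cell markers 1 fall of 9 (0, median 0.52), and erythroid (13 genes, median 0.53) and megakaryocyte markers (6 genes, median -0.17) 0 of either. Camera adjusted p, with an estimated correlation, was 0.0858 (hepatocyte), 0.147 (endothelial), 0.243 (macrophage), 0.304 (neutrophil), 0.529 (T and NK), 0.619 (stellate), 0.913 (cholangiocyte), 0.726 (B and plasma), 0.607 (erythroid) and 0.839 (megakaryocyte). The hepatocyte set passed without infected control replicate 10 (camera adjusted p = 0.0371).

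Of the 20 preset genes, SAA3 (listed as HPS5), HP and HK2 rose and PKLR, BDH1, CYP7A1 and the bile acid receptor NR1H4 (-0.71 ± 0.13) fell with infection. The other preset genes reported here did not pass edgeR's test. Among cytokines, group means ran from 0.105 ± 0.149 CPM (uninfected control) to 3.01 ± 4.62 CPM (uninfected BHB) for IL6, from 0.13 ± 0.184 to 15.2 ± 30.5 CPM for IL1B and from 0.314 ± 0.0762 to 5.69 ± 10.4 CPM for TNF in these same groups. CXCL8 ran from 1.84 ± 0.892 CPM in uninfected control to 415 ± 819 CPM in uninfected RG libraries. The high means rested on 1 library each. Without uninfected BHB replicate 2 the means of that group were 0.731 CPM for IL6, 0 for IL1B, 0.485 for TNF and 1.97 for CXCL8 (347 CPM with it), and without uninfected RG replicate 3 the CXCL8 mean of uninfected RG libraries was 5.62 ± 8.37 CPM. The 2 uninfected control libraries had 0.21 and 0 CPM of IL6 and 0 and 0.26 CPM of IL1B, and without replicate 2 CXCL8 was at 1.21 CPM. CRP ran from 221 ± 140 CPM in uninfected RG to 371 ± 159 CPM in infected control libraries. TXNIP ran from 126 ± 47.5 CPM in uninfected BHB to 224 ± 68.8 CPM in infected control libraries, and PDK4 from 27.6 ± 18.7 CPM in infected control to 110 ± 92 CPM in uninfected RG libraries (69 ± 52.9 without replicate 4). CPT1A ran from 104 ± 41.3 CPM (uninfected BHB) to 154 ± 37.6 CPM (infected RG), and OXCT1, which hepatocytes barely express, from 3.5 ± 2.07 CPM (infected control) to 6.95 ± 2.85 CPM (uninfected control). PCK1 ran from 188 ± 60.8 CPM in uninfected control to 1690 ± 481 CPM in uninfected RG libraries, and FGF21 from 6.54 ± 2.69 CPM in uninfected RG to 70.9 ± 52.4 CPM in infected control libraries. Leaving out 1 library moved IL1B (3.25 without uninfected BHB replicate 2, edgeR adjusted p = 0.0121), CXCL8 (-2.33 without infected RG replicate 8, 0.00946) and PDK4 (-0.78 without uninfected RG replicate 3, 0.0422) past the threshold. OXCT1 passed without infected control replicate 2 (-0.72, edgeR adjusted p = 0.0305) or 7 (-0.60, 0.0243). OXCT1 also passed with RLE normalization, in DESeq2, with a spline of library number and without the 4 libraries that stood apart. TXNIP passed with surrogate variables.

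To ask what infection did under each regimen, the effect was tested within control, BHB and RG libraries. Under RG, CXCL11 (6.16 ± 1.18) and OASL (6.15 ± 0.98) were among the largest rises and GSTA1 (-4.42 ± 0.70), NGFR (-4.39 ± 0.44) and the lipogenic gene THRSP (-3.99 ± 0.73) fell most, with an edgeR adjusted p of at most 0.000276 and 12 of 12 infected libraries on the called side for each. Under BHB, CXCL11 (4.92 ± 1.10) and ISG20 (4.66 ± 0.65) rose and AADAC (-4.12 ± 0.89) fell in 13 of 13 infected libraries, with an edgeR adjusted p of at most 0.0035. CXCL8 (-5.34 ± 1.24) and RND1 (-3.59 ± 1.07) were also called lower, but without uninfected BHB replicate 2 their log2 fold changes were 2.12 (edgeR adjusted p = 0.548) and 2.74 (0.313). Under the control regimen, CXCL11 (8.10 ± 1.86), OASL (5.98 ± 1.34) and SAA3 (listed as HPS5, 5.59 ± 1.27) rose and the carotenoid oxygenase BCO1 (-2.95 ± 0.51), HSD17B6 (-3.01 ± 0.60) and RIMS2 (-3.13 ± 0.77) fell in 13 of 13 infected libraries, with an edgeR adjusted p of at most 0.0428. In total 1036 genes rose and 1244 fell under RG, 367 and 606 under BHB, and 31 and 51 under control (edgeR quasi-likelihood, adjusted). With surrogate variables rises outnumbered falls in each, at 1801 and 1489 under RG, 1720 and 1255 under BHB, and 152 and 93 under control.

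The counts within a regimen rested on few uninfected libraries. Under RG, 1402 genes passed without uninfected replicate 1 and 1257 without replicate 4, and under BHB 643 without uninfected replicate 2 and 447 without replicate 4. Under control, 3 genes passed without uninfected replicate 1 and 7 without replicate 2. Without infected control replicates 1, 4, 5, 6, 8 and 11 the counts were 47, 52, 53, 50, 49 and 47, and without replicates 2, 10 and 12 they were 193, 354 and 135. CXCL11, OASL, SAA3 (listed as HPS5) and HSD17B6 did not pass without uninfected control replicate 1 (edgeR adjusted p = 0.678, 0.321, 0.685 and 0.482) or 2 (0.564, 0.582, 0.499 and 0.105), nor BCO1 without replicate 1 (0.17). RIMS2 did not pass without uninfected control replicate 1 (edgeR adjusted p = 0.408) or 2 (0.673), or without infected control replicates 1, 4, 5, 6, 8, 9 or 11 (0.0566 to 0.0602). DESeq2 called 370 genes higher and 105 lower under control, 77.9% higher against 37.8% in edgeR. The interaction of regimen with infection gave 0 genes in edgeR, with 363 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.478, so a difference of the infection effect between regimens was not shown. DESeq2 gave 2 genes and limma-voom 14 for that interaction.

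To identify whether restricted glucose changed the infected liver, RG was compared with control among infected libraries. RG led to an increase in the amino acid metabolism genes SDS by 17-fold, HPD by 7.81-fold and GNMT by 7.47-fold, and the sulfotransferase gene SULT2A1 rose from 103 ± 89.6 to 1140 ± 557 CPM. The urea cycle gene ASS1 rose by 4.59-fold, from 221 ± 93.4 CPM (SD, n = 13) to 1010 ± 388 CPM (n = 12), and the gluconeogenic genes FBP1, G6PC1 and PCK1 by 6.69-fold, 5.63-fold and 4.22-fold. PSAT1 fell from 284 ± 136 to 38.3 ± 25.6 CPM (7.43-fold) and PSPH was 4.66-fold lower. The hormone gene FGF21 was 6.27-fold lower and ANGPTL8, an insulin-responsive secreted factor, 10.2-fold lower. In edgeR's quasi-likelihood test 278 genes were higher and 248 lower (adjusted), 162 and 119 of them by more than 1 log2 unit.

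In detail, the largest rises of RG over control were SDS (4.09 ± 0.64), SLPI (3.63 ± 0.75), SULT2A1 (3.47 ± 0.35, edgeR adjusted p = 4.14e-09, 12 of 12 RG libraries above the control mean), SHD (2.98 ± 0.52), HPD (2.97 ± 0.37), GNMT (2.90 ± 0.40) and PRR29 (2.83 ± 0.59), with an edgeR adjusted p of at most 0.00195. CSF3 (2.85 ± 0.76), CCK (2.84 ± 0.74) and ETNPPL (2.74 ± 0.74) were also called, but the edgeR adjusted p of CSF3 was 0.791 without infected RG replicate 8, that of CCK 0.324 without replicate 5 and that of ETNPPL 0.0615 without replicate 3. The largest falls were ANGPTL8 (-3.35 ± 0.59), CHAC1 (-3.15 ± 0.69), PSAT1 (-2.89 ± 0.36), FGF21 (-2.65 ± 0.46), THRSP (-2.64 ± 0.60) and LOXL4 (-2.43 ± 0.33). PSPH (-2.22 ± 0.34), FUT1 (-2.21 ± 0.37), AJUBA (-2.09 ± 0.41) and PEG10 (-2.05 ± 0.48) followed, with an edgeR adjusted p of at most 0.0075 for all 10, and each was lower in at least 10 of 12 RG libraries. PEG10 did not pass with the replicate number as a block (-1.91, edgeR adjusted p = 0.0599) or with the compared groups alone (0.0547). Of the preset genes, PCK1 rose and FGF21 fell, and HP rose by 0.65 ± 0.19 on the log2 scale. HP did not pass without infected control replicate 1, 2, 3, 4, 10 or 11 or RG replicate 3, 5, 7, 8, 10 or 11 (edgeR adjusted p from 0.0504 to 0.077), nor without the count filter (0.0552), without infected control replicates 7 and 10 (0.0781) or in limma-voom (adjusted p = 0.0515). The other preset genes reported here did not pass in the main fit. PDK4 passed without infected control replicate 1 or 10 or RG replicate 7 or 8 (edgeR adjusted p = 0.0489, 0.0111, 0.0499 and 0.035). PDK4 also passed in DESeq2, with the replicate number as a block, a spline of library number or surrogate variables, and without the 4 libraries that stood apart. NR1H4 likewise passed without infected control replicate 5 or 7 or RG replicate 9 or 13 (edgeR adjusted p = 0.0359, 0.00557, 0.0336 and 0.027). NR1H4 passed too in DESeq2, with surrogate variables and without the 4 libraries, and CXCL8 passed without the 4 libraries.

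Among the lists, 3 passed in RG minus control. Urea cycle and amino acid catabolism had 10 rises and 1 fall of 17 (12 and 1 adjusted over the list alone, median 0.88, camera adjusted p = 6.31e-05 with an estimated correlation), with ASS1 at 2.20 ± 0.23, ARG1 at 1.72 ± 0.19 and ASL at 2.11 ± 0.29, and a fall in GLUD1. ATF4 targets, genes of the amino acid and ER stress response, had 12 falls and 1 rise of 21 (14 and 1, median -0.82, camera adjusted p = 6.31e-05), with SESN2 at -1.93 ± 0.28 and TRIB3 at -2.03 ± 0.31, and a rise in CTH. Gluconeogenesis had 4 rises of 12 (8, and 1 fall, over the list alone, median 0.41, camera adjusted p = 0.00237), with FBP1 at 2.74 ± 0.34, PCK1 at 2.08 ± 0.35 and G6PC1 at 2.49 ± 0.50. Cholesterol synthesis had 9 falls and 1 rise of 24 (12 and 1 over the list alone, median -0.59) but camera adjusted p = 0.102 with an estimated correlation, with CYP51A1 at -1.35 ± 0.21 and INSIG1 at 1.63 ± 0.27. Neutrophil markers had 2 rises of 13 (6 over the list alone, median 0.92, camera adjusted p = 0.102), and this set passed without infected RG replicate 8 (0.037). The edgeR adjusted p of S100A9 (1.13 ± 0.30) was 0.0654 without infected RG replicate 4 and 0.0506 with the replicate number as a block. Macrophage markers had 1 rise of 15 (3, median 0.25, camera adjusted p = 0.165), CD5L at 1.32 ± 0.24, and hepatocyte markers 1 rise of 12 (1, median 0.06, 0.451), HPD. Median, mean and camera's direction differed for complement (0.10, -0.12, down), glucose-responsive genes (0.09, -0.05, up), glucocorticoid targets (0.06, -0.11, down) and endothelial markers (-0.08, -0.04, up). Acute phase proteins had 4 rises of 20 (6 over the list alone, median 0.34, camera adjusted p = 0.182), with SAA4, of a multigene family, at 2.47 ± 0.46. The interferon list had 0 of 34 (0, median 0.21, camera adjusted p = 0.705). Differences in list score had an unadjusted 95% interval on 1 side of 0 for 17 of 39 lists and marker sets. Among markers, the hepatocyte set was 1 of these (0.38, 0.13 to 0.62), but it holds HPD and its median change was 0.06. The other marker sets were neutrophil (0.83, 0.46 to 1.2), T and NK cell (0.56, 0.21 to 0.91), megakaryocyte (0.44, 0.09 to 0.78) and macrophage (0.36, 0.18 to 0.54). The other lists, besides those that passed camera, were glycolysis (0.66), acute phase (0.49), ketone body (0.47), xenobiotic (0.43), insulin (0.30), fatty acid oxidation (0.24), TCA cycle (0.22), cholesterol (-0.45) and oxidative phosphorylation genes (0.30). The last had an interval that included 0 without infected control replicate 7 or 11 or RG replicate 3, 5, 6 or 7. Below and above library number 861.5 the differences were 0.65 and 0.17 (xenobiotic), 0.52 and 0.19 (oxidative phosphorylation), 0.44 and 0.14 (insulin) and 0.25 and 0.09 (TCA cycle). Others changed less in proportion to their size, with 1.21 and 0.91 (urea cycle), -1.23 and -0.97 (ATF4) and 1.39 and 1.19 (gluconeogenesis).

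To identify whether the ketone body regimen changed the infected liver, BHB was compared with control among infected libraries. BHB led to an increase in HPD, of tyrosine breakdown, by 12-fold, in SDS by 10.9-fold, in the glutamate transporter SLC1A2 by 10.1-fold and in the sulfotransferase genes SULT1A3 and SULT2A1 by 7.25-fold and 6.91-fold. ASS1 rose by 4.21-fold to 929 ± 256 CPM (SD, n = 13), and G6PC1, FBP1 and PCK1 by 6.67-fold, 5.26-fold and 3.92-fold. ANGPTL8 was 13.4-fold lower, FGF21 8.44-fold lower and PSAT1 4.86-fold lower. PDK4, which restrains pyruvate oxidation, rose from 27.6 ± 18.7 to 71.3 ± 32.3 CPM (2.58-fold). In edgeR's quasi-likelihood test 400 genes were higher and 560 lower (adjusted), 161 and 257 of them by more than 1 log2 unit. Rises did not stay fewer than falls in limma-voom (1089 and 1087) and with surrogate variables (1467 and 1260), and with the replicate number as a block the counts were 590 and 592.

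**Figure D2:**
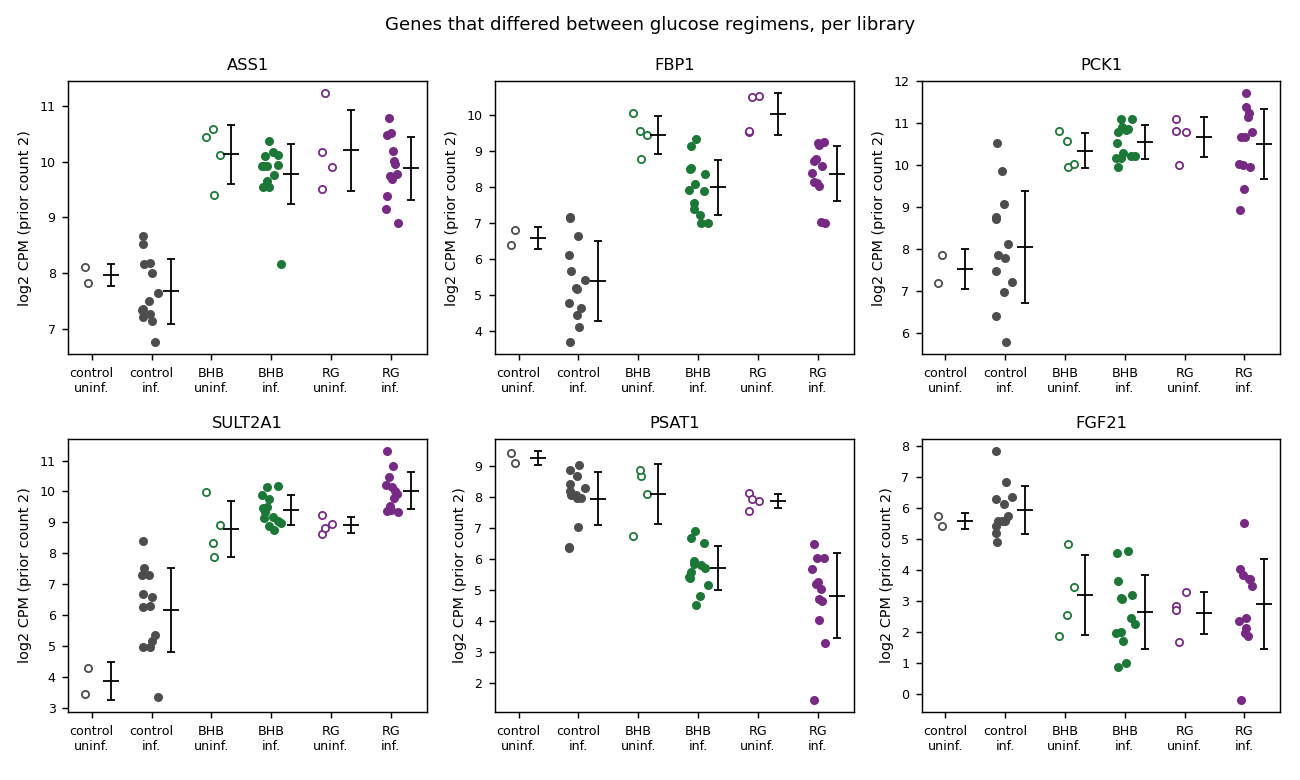
Log2 CPM of ASS1, FBP1, PCK1, SULT2A1, PSAT1 and FGF21 in each library by group, with open circles for uninfected libraries, filled circles for infected libraries and black bars for mean ± SD. ASS1 lay between 6.76 and 8.67 in infected control libraries, between 8.17 and 10.38 in infected BHB libraries and between 8.90 and 10.79 in infected RG libraries.

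The largest rises of BHB over control were HPD (3.58 ± 0.38, edgeR adjusted p = 1.08e-08, 13 of 13 BHB libraries above the control mean), SLPI (3.46 ± 0.74), SDS (3.45 ± 0.62), SLC1A2 (3.34 ± 0.53), SHD (2.99 ± 0.52) and SULT1A3 (2.86 ± 0.28). SULT2A1 (2.79 ± 0.34), G6PC1 (2.74 ± 0.50), GNMT (2.70 ± 0.39) and SPOCK1 (2.62 ± 0.35) followed, with an edgeR adjusted p of at most 0.00223 for all 10 and at least 12 of 13 BHB libraries higher. Among the largest falls were ANGPTL8 (-3.74 ± 0.58), FGF21 (-3.08 ± 0.46), CHAC1 (-3.05 ± 0.67) and STC2 (-2.60 ± 0.49), then PEG10 (-2.49 ± 0.48) and FUT1 (-2.43 ± 0.36), with an edgeR adjusted p of at most 0.00286. GADD45G (-2.54 ± 0.61) was called too, but its edgeR adjusted p was 0.291 without infected control replicate 7, where its log2 fold change was -0.74. Of the preset genes, HP (0.77 ± 0.18, edgeR adjusted p = 0.00602), PCK1 (1.97 ± 0.34) and PDK4 (1.37 ± 0.35) rose and FGF21 fell. The other preset genes reported here did not pass in the main fit. TXNIP passed without infected BHB replicate 8 (edgeR adjusted p = 0.0422), with a spline of library number and with surrogate variables. NR1H4 passed without infected control replicate 7 (edgeR adjusted p = 0.0367), with surrogate variables and without the 4 libraries that stood apart.

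The lists that passed in BHB minus control were those of RG minus control. Urea cycle and amino acid catabolism had 10 rises and 1 fall of 17 (10 and 1 adjusted over the list alone, median 1.05, camera adjusted p = 0.00105 with an estimated correlation), with ARG1 at 1.48 ± 0.19 and ASL at 1.79 ± 0.28. ATF4 targets had 12 falls and 1 rise of 21 (16 and 1, median -1.02, camera adjusted p = 0.00105), with SESN2 at -1.90 ± 0.27 and TRIB3 at -1.75 ± 0.30. Gluconeogenesis had 5 rises of 12 (8, median 0.42, camera adjusted p = 0.00485). Cholesterol synthesis had 11 falls and 1 rise of 24 (14 and 1, median -0.78, camera adjusted p = 0.137), with MSMO1 at -1.90 ± 0.31 and SQLE at -1.68 ± 0.29, and this list passed without infected control replicate 7 (0.0495). Negative acute phase proteins had 4 falls of 11 (4, median -0.34, camera adjusted p = 0.524), such as SERPINA6 (-1.32 ± 0.31), and nuclear oxidative phosphorylation 6 rises of 42 (9, median 0.29, 0.497), such as ATP5F1D (0.61 ± 0.15). The interferon list had 0 of 34 (0, median -0.63, camera adjusted p = 0.72) and neutrophil markers 2 rises of 13 (2, median 0.56, 0.478). Median, mean and camera's direction differed for glucose-responsive genes (-0.23, -0.25, up), PPARA targets (0.06, -0.26, down), ketone body genes (-0.06, 0.35, up), bile acid genes (-0.16, 0.06, down) and hypoxia genes (0.01, -0.05, up). They differed also for erythroid (0.03, 0.03, down), hepatocyte (-0.14, 0.25, up) and cholangiocyte markers (0.06, -0.14, down). Of 39 score differences 19 had an unadjusted 95% interval on 1 side of 0. Among markers, the hepatocyte set was 1 of these (0.32, 0.08 to 0.56), but it holds HPD and its median change was -0.14. The other marker sets were neutrophil (0.56, 0.2 to 0.92), T and NK cell (0.48, 0.14 to 0.83), stellate (0.41, 0.07 to 0.76), B and plasma cell (0.29, 0.07 to 0.5) and macrophage (0.25, 0.07 to 0.42). The other lists, besides those that passed camera, were glycolysis (0.51), xenobiotic (0.49), chaperone (0.43), acute phase (0.35, 0.18 to 0.53), oxidative phosphorylation (0.30), antioxidant (0.26), insulin (0.26), TCA cycle (0.26), glucocorticoid (-0.27) and cholesterol genes (-0.54). The glucocorticoid list holds ANGPTL8, 1 of the largest falls of this comparison, and its score without ANGPTL8 was not computed. Below and above library number 861.5 the differences were 0.79 and 0.15 (xenobiotic), 0.49 and 0.18 (oxidative phosphorylation), 0.46 and 0.1 (hepatocyte) and 0.33 and 0.1 (TCA cycle). Others changed less in proportion to their size, with 1.17 and 0.94 (urea cycle), -1.03 and -0.93 (ATF4), 1.32 and 1.27 (gluconeogenesis) and 0.55 and 0.58 (neutrophil). The interval included 0 for stellate markers without infected control replicate 7, for oxidative phosphorylation without that library or BHB replicate 1 or 6, and for chaperones without infected control replicate 1, 3, 4, 5, 6, 7, 8, 9, 10 or 11 or BHB replicate 1, 2, 3, 8, 9, 10 or 11.

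To compare the responses to both low-glucose regimens, the genes called in RG minus control and in BHB minus control were overlaid. SDS, HPD, SULT2A1, ASS1, ARG1, FBP1, G6PC1 and PCK1 were higher and PSAT1, FGF21, ANGPTL8 and CHAC1 lower in both. In total 338 genes passed in both with the same direction, 164 higher and 174 lower, and 0 with opposite directions, where independent lists would share 7.3 and 9.1. Both comparisons used the same control libraries. Over 12304 genes with a mean of at least 1 CPM, the fold changes correlated at 0.678 with a covariance of 0.138, against 0.488 and 0.0362 when unchanged groups were simulated against these controls, and the largest simulated overlap was 0 in 20 runs. The simulation drew each gene independently. Unchanged groups leave few genes to call, so a simulated overlap of 0 was nearly fixed in advance and is no yardstick for 338. With the controls split so that each comparison had its own, the median overlap over 20 splits was 106.5 genes (71 to 127, 3.3 for independent lists). The median correlation was 0.389 and the median covariance 0.094 (0.0339 to 0.1225). These correlations are across genes, which are not independent replicates.

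**Figure D3:**
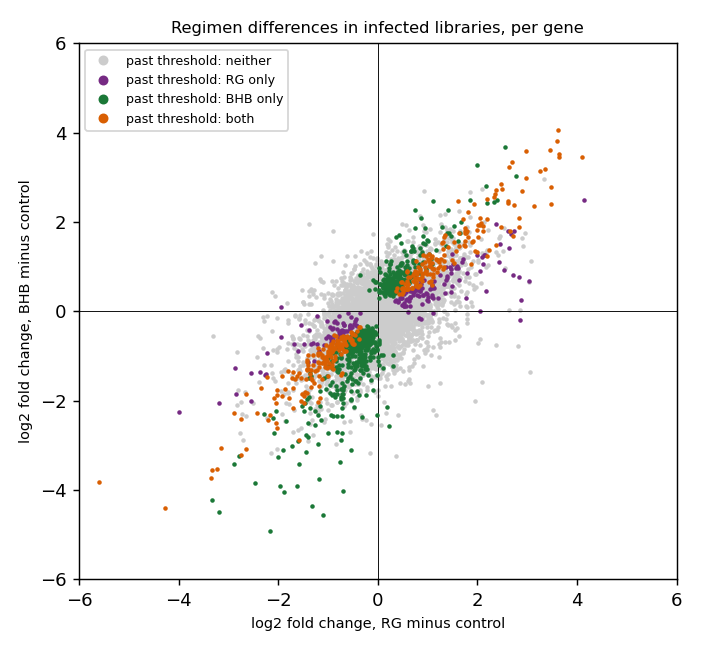
Log2 fold change of RG minus control (x axis) against BHB minus control (y axis) in infected libraries, 1 point per gene, coloured by the comparison in which it passed the edgeR threshold. Of the plotted genes 334 passed in both comparisons, 188 in RG minus control alone, 622 in BHB minus control alone and 14120 in neither, and 10 genes with 0 counts in an infected group were left out.

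To ask whether adding BHB to a low glucose supply made a difference, BHB was compared with RG among infected libraries. C1RL, a complement-related serine protease gene, was lower in BHB at 10.4 ± 2.71 CPM (SD, n = 13) against 21.5 ± 6.03 CPM (n = 12), a log2 fold change of -1.05 ± 0.18 (edgeR adjusted p = 0.00714). PALM3 was higher at 84.4 ± 30.3 against 37.3 ± 12.6 CPM (1.18 ± 0.22, edgeR adjusted p = 0.0269), and the kinase anchor gene AKAP7 lower at 18.7 ± 6.12 against 36.6 ± 15.6 CPM (-0.97 ± 0.19, 0.034), each in 13 of 13 BHB libraries. These 3 genes were the calls of edgeR's quasi-likelihood test, with 1628 genes at an unadjusted p under 0.05, while DESeq2 called 56 and limma-voom 516. PALM3 did not pass without infected RG replicate 6, 7, 9, 10 or 13 (edgeR adjusted p from 0.0677 to 0.0808). AKAP7 did not pass without infected RG replicate 6, 7, 8, 9, 10 or 13 or BHB replicate 1, 2, 3, 5, 8, 10 or 11 (0.0689 to 0.202), nor with the compared groups alone (0.0557), a spline of library number (0.0585) or surrogate variables (0.0877). The count was 1 without infected RG replicate 6, 7, 9, 10 or 13, 5 without RG replicate 3 or 11, 6 without BHB replicate 6 and 7 without BHB replicate 7. None of the 39 lists passed camera. The interferon list had a median of -0.64 (0 of 34 genes, 8 lower adjusted over the list alone, camera adjusted p = 0.662) and cytokine genes a median of -0.85 (0 of 32, 9 lower over the list alone, 0.795). The unadjusted 95% interval of the score difference lay on 1 side of 0 for 5 of 39 lists, interferon (-0.77, -1.46 to -0.08), cytokine (-0.61, -1.16 to -0.06), negative acute phase (-0.49, -0.86 to -0.12), coagulation (-0.31, -0.54 to -0.07) and antioxidant genes (0.16, 0.03 to 0.29). It included 0 for interferon without infected BHB replicate 2 or 11 or RG replicate 6 or 13, and for cytokine genes without BHB replicate 3 or RG replicate 8, 10 or 13. Below and above library number 861.5 the differences were -0.24 and -0.83 for cytokine genes and -0.73 and -0.78 for interferon genes. The urea cycle, ATF4 and gluconeogenesis medians were -0.04, 0.10 and 0.02. Median or mean and camera's direction differed for gluconeogenesis (mean -0.03, up), xenobiotic metabolism (-0.07, -0.09, up), T and NK cell markers (median 0.03, mean -0.14, down) and oxidative phosphorylation (median 0, mean -0.02, up). None of the 20 preset genes passed.

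To ask whether the regimens differed without infection, the uninfected libraries were compared. In RG, SULT2A1 was 32.2-fold higher than in control (487 ± 87.5 against 15.1 ± 6.2 CPM, SD, n = 4 and 2), SULT1A3 22.1-fold and the metallothionein gene MT1A 29.5-fold higher. The folate enzyme gene MTHFD1L was 7.10-fold, LAX1 7.26-fold and the peptide transporter SLC15A1 6.80-fold lower. In BHB, MT1A, SULT2A1 and SULT1A3 were 75.8-fold, 33.8-fold and 24.4-fold higher, SRPX was 5.43-fold lower and SLC15A1 stood at -3.47 ± 0.58 on the log2 scale. The direction held in 4 of 4 libraries for each gene except MT1A in RG (3 of 4), and sulfotransferase and metallothionein genes belong to families that can share reads. In edgeR's quasi-likelihood test 8 genes were higher and 8 lower in RG (1094 at an unadjusted p under 0.05), and 6 and 2 in BHB (981). DESeq2 gave 106 and 78 genes, limma-voom 1204 and 289. In RG, urea cycle and amino acid catabolism (median 1.27, 2 rises of 17, 8 and 1 fall adjusted over the list alone) and gluconeogenesis (median 0.85, 0 of 12, 4 over the list alone) passed camera, with adjusted p = 0.00199 and 0.0115 with an estimated correlation. In BHB these lists passed too (median 0.90, 1 of 17, 7 and 1 fall over the list alone, camera adjusted p = 0.002; median 0.61, 0 of 12, 4 over the list alone, 0.0161). Cholesterol synthesis was lower in BHB (median -1.09, 0 of 24, 12 falls and 1 rise over the list alone, camera adjusted p = 0.0471).

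These calls rested on 2 uninfected control libraries. Without control replicate 1 or 2, RG minus control gave 2 and 0 genes and BHB minus control 0 and 0, and without RG replicate 2 or 4 the former gave 6 and 3. SULT2A1 and SULT1A3 in RG had an edgeR adjusted p of 0.215 and 0.215 without control replicate 1 and 0.803 and 0.339 without replicate 2, and in BHB 0.382 and 0.382, then 0.544 and 0.116. MT1A had 0.499 and 1 in RG and 0.709 and 0.535 in BHB (edgeR adjusted p), and in RG also 0.0653, 0.0715 and 0.103 without RG replicates 2, 3 and 4. MTHFD1L had an edgeR adjusted p of 0.462 without control replicate 2 and 0.0568 without RG replicate 4. SLC15A1 in RG did not pass without control replicate 1 or 2 (edgeR adjusted p = 0.215 and 0.485) or RG replicate 1, 2 or 4 (0.0708, 0.0653 and 0.113), nor LAX1 without control replicate 1 or 2 (0.298 and 0.636) or RG replicate 1, 3 or 4 (0.124, 0.116 and 0.151). In BHB, SLC15A1 and SRPX had 0.0728 and 0.0728 without control replicate 1 and 0.0535 and 0.369 without replicate 2 (edgeR adjusted p). The gluconeogenesis list in RG gave camera adjusted p = 0.0648 without RG replicate 4, and the cholesterol list in BHB gave 0.176 without control replicate 1, 0.111 without BHB replicate 2 and 0.184 without BHB replicate 3. BHB minus RG in uninfected libraries gave 0 genes in edgeR (499 at an unadjusted p under 0.05, smallest adjusted p 0.879), 0 in DESeq2 and 2 in limma-voom.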

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

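The tests of the explanations weighed here for infected control replicate 10, for the cytokine transcripts of 2 uninfected libraries and for the overlap of regimen genes were chosen after the results were seen, while the counts over other splits of the libraries were fixed before. In addition, 2 of these tests were rewritten after their first outcome had been seen, the one on depth and complexity and the one on neutrophils, and both outcomes are given.

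Infected control replicate 10 had interferon transcripts at the level of uninfected liver, with a list score of -1.942 against -3.273 to -1.399 in the 10 uninfected libraries and -0.55 to 1.925 in the other 12 infected control libraries. Low depth or complexity was argued against, since 0 of 4 measures lay beyond those 12 libraries on the poor side (16.99 M counts, mitochondrial share 4.74% against 4.98% to 34.3%, 13221 genes with 10 or more counts against 11546 to 12926). The first form of this test asked whether any measure lay outside the range on either side, counted 2 of 4, both on the good side, and had been read as in favour of that explanation. A swap with an uninfected control library was argued against too, because over 702 genes that changed with infection in BHB and RG, interferon genes left out, the higher uninfected control library scored -0.992, below the lowest of the other 12 (-0.326). A single wrong label stays open, since replicate 10 scored -1.004, inside the uninfected range of -1.678 to -0.942 (SD 0.273), and a weak response or a failed infection of that pig, which the labels do not record, may give the same value and was not tested.

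Uninfected BHB replicate 2 and uninfected RG replicate 3 had cytokine scores of 2.915 and 2.867, against at most 0.309 in the other 8 uninfected libraries. In CPM of total counts, without the TMM factors used elsewhere, CXCL8 stood at 1480 and 1540 CPM (others 0.409 to 15.2) and CCL20 at 1130 and 2040 CPM (others 0 to 24.6). More neutrophils in the piece were argued against, since the neutrophil marker score rose over the median of the other 8 by -0.02 and 0.057 and the cytokine score by 4.386 to 4.434, a difference of at most -4.377 (SD of the marker score 0.783), with S100A9 at 18.9 and 17.6 CPM (others 4.2 to 55.4) and S100A8 at 6.02 and 7.57 CPM (others 2.13 to 17.9). The first form of this test compared the lower neutrophil rise, -0.02, with 0, which lay within the spread, and had been read as against neutrophils. A library batch stays open, since the 6 libraries with the nearest numbers had a median cytokine score of 0.462, above the upper quartile of all libraries (0.412, median -0.066). These 6 scores ran from -1.155 to 1.044, below both libraries, and the uninfected libraries with numbers between the 2 had 0.309 (RG replicate 2) and -1.155 (BHB replicate 3), so a batch along these numbers would have to spare its neighbours. An inflamed liver in an uninfected animal may give the same values, and the design gives no group for it, so that explanation was not tested.

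The overlap of 338 genes between RG minus control and BHB minus control was weighed against shared controls and against library number. The shared controls were argued against as the whole cause, since the 20 fits with separate controls gave 71 to 127 shared genes against a median of 3.3 for independent lists. The covariance of the fold changes exceeded the simulated mean by 0.102 (simulated SD 0.00148). That simulation drew each gene independently, so its SD leaves out the correlation between genes and cannot serve as a yardstick. With separate controls the covariance ran from 0.0339 to 0.1225. Library number was argued against as well, since a spline of it left 461 shared genes. Of 100 splits of the libraries 1, the real one, gave as many shared genes, and the highest of the others gave 0. Shuffled groups leave few genes to call in either comparison, so these splits cannot tell shared controls from a shared response. A hypothesis consistent with these values is that the low glucose supply common to both regimens gave the shared response, which the design cannot separate from other features common to both.

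Other splits of the same libraries were counted for each comparison with at least 3 libraries per group. The labels were shuffled without regard to library number, which showed a structure, so these shares can make chance unlikely but cannot exclude it. For BHB minus control in infected libraries, 1 of 100 splits gave as many genes as the real one (960, highest other 4). As many lists came from 1 of 100 (3, highest other 2), so a chance split was unlikely there. For RG minus control, 2 of 100 splits gave as many genes (526, highest other 722) and 2 of 100 as many lists (3, highest other 3). These shares lay under 0.05, but another split of these libraries separated more genes. For BHB minus RG in infected libraries, 1 of 100 splits gave as many genes (3, highest other 1), and with 0 real lists all 100 gave as many (highest other 1). For infection, 1 of 100 splits gave as many genes averaged over regimens (4173, highest other 2338), in BHB (973, highest other 9) and in RG (2280, highest other 38.4% of that count), and all 100 gave as many lists (0, highest other 3). For BHB minus RG in uninfected libraries all 35 splits gave as many genes as the real count of 0 in edgeR, where 499 genes had an unadjusted p under 0.05 and DESeq2 gave 0 and limma-voom 2. The highest of those splits called 339 genes, which points to a structure of these 8 libraries other than regimen.

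In the groups of 4 libraries, 35 of 542 values lay far from the other 3 by Dixon's criterion at the 95% level, where chance gives about 1 in 20. Uninfected BHB replicate 1 held 10 of them. Its bile acid score was -0.403 (others 0.78 to 0.892), and its log2 CPM was 7.1 for ANGPTL4, 6.81 for SLCO1B3, 9.36 for NUPR1, 4.36 for KDM3A and -0.82 for CSF3R. In the same library SDS stood at 9.03 (others 3.4 to 4.32), CYP2A19 at 2.14, ENO2 at 1.86 and C1RL at 3.75. Uninfected BHB replicate 2, besides its cytokine score of 2.915, had a log2 CPM of 10.43 for CXCL8 (others 0.3 to 1.72), 5.93 for IL1B, 5.92 for SESN2, 2.08 for SESN3 and 1.68 for SAA4 (others 5.97 to 6.34). Uninfected BHB replicate 4 had ELOVL6 at 7.32 (others 5.3 to 5.55). Uninfected RG replicate 1 had a mitochondrial share of 16.81% (others 5.79% to 6.67%) and log2 CPM of 8.3 for CYP27A1, 0.85 for ANGPTL8, 6.84 for CYP2C33, 11.06 for TTR and 5.4 for CYP4A24. Uninfected RG replicate 3 had a coagulation score of 0.762 (others 0.538 to 0.548) and log2 CPM of -1.41 for AADAC (others 3.43 to 4.28), 1.57 for CX3CR1, 2.01 for LCN2 and 5.93 for SERPINA6. In that library SESN3 stood at 2.46, NQO1 at 3.12, TEK at 4.76 and CYP51A1 at 5.77. Uninfected RG replicate 4 had SLC37A4 at 8.38, ACAA2 at 4.93 and INSIG1 at 7.88 (others 9.11 to 9.3).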

How the results depend on the processing

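The fits without the robust option, without 4 libraries that stood apart (infected control replicates 7 and 10, uninfected BHB replicate 1, uninfected RG replicate 1), without the 2 infected control libraries among them, and the lists with each library left out were chosen after the data were seen, as was the restriction of fitted fold changes to genes past the threshold. The number of values examined for far libraries changed with that restriction. RLE normalization and fits without the robust option moved no count by over 1.5 times. The causes of the moves given here were not tested, except that a test against a fold change of 1.5 asks for larger changes and that fits of fewer libraries have less information.

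For infection averaged over regimens (4173 genes), limma-voom gave 6956 and the test against a fold change of 1.5 gave 1117. For infection under control (82 genes), the counts were 54 without a filter, 475 in DESeq2, 2677 in limma-voom, 2 with the compared groups alone, 409 with a spline of library number, 245 with surrogate variables, 17 against a fold change of 1.5, 493 without the 4 libraries and 378 without the 2 control libraries. Under BHB (973 genes), limma-voom gave 1899, surrogate variables 2975 and the fold change test 249, and under RG (2280 genes) limma-voom gave 5145 and the fold change test 752. RG minus control in infected libraries (526 genes) went to 1043 in limma-voom, 349 with the compared groups alone, 1768 with surrogate variables, 93 in the fold change test and 927 without the 4 libraries. BHB minus control (960 genes) went to 2176 in limma-voom, 2727 with surrogate variables and 136 in the fold change test. BHB minus RG in infected libraries (3 genes in edgeR, 1628 at an unadjusted p under 0.05) gave 56 in DESeq2, 516 in limma-voom, 18 with the compared groups alone, 43 with surrogate variables, 0 in the fold change test, 14 without the 4 libraries and 9 without the 2 control libraries. In uninfected libraries RG minus control (16 genes) gave 6 without a filter, 106 in DESeq2, 1204 in limma-voom, 1 with the compared groups alone, 87 with the spline, 459 with surrogate variables, 4 in the fold change test, 31 without the 4 libraries and 35 without the 2 control libraries. BHB minus control there (8 genes in edgeR, 981 at an unadjusted p under 0.05) gave 78 in DESeq2, 289 in limma-voom, 0 with the compared groups alone, 61 with the spline, 293 with surrogate variables and 15 without the 2 control libraries. BHB minus RG there (0 genes in edgeR, 499 at an unadjusted p under 0.05, 0 in DESeq2) gave 2 in limma-voom, and the interaction (0 in edgeR, 363 unadjusted) gave 2 in DESeq2, 14 in limma-voom and 1 with surrogate variables. Over these settings the share of rises among called genes ran from 46.7% to 58.3% for infection averaged over regimens, from 30.1% to 77.9% under control, from 31.1% to 57.8% under BHB, from 38.8% to 54.7% under RG, from 48.9% to 64.5% for RG minus control and from 38.7% to 53.8% for BHB minus control in infected libraries. The overlap of 338 genes went to 617 in limma-voom, 1209 with surrogate variables, 62 in the fold change test and a median of 106.5 with the controls split.

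With a preset correlation, camera called 23 lists for infection, 16 for RG minus control, 17 for BHB minus control and 5 for BHB minus RG, and fry called 23, 14, 15 and 0, where the estimated correlation gave 0, 3, 3 and 0. Urea cycle, ATF4 and gluconeogenesis lists passed in all 31 settings of RG minus control (highest camera adjusted p = 0.000896, 0.000747 and 0.00885) and all 32 of BHB minus control (0.00508, 0.00508 and 0.0103). In uninfected libraries the urea cycle list passed in all 12 settings of each regimen (highest camera adjusted p = 0.0335 in RG and 0.038 in BHB), gluconeogenesis in 10 (RG, highest 0.0695) and 11 (BHB, 0.106), and cholesterol synthesis in BHB in 7 (0.256).

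With each library left out in turn, the counts ranged from 2452 to 4565 (infection averaged), 3 to 354 (control), 447 to 1029 (BHB), 1257 to 2528 (RG), 397 to 734 (RG minus control, infected), 730 to 1070 (BHB minus control, infected), 1 to 7 (BHB minus RG, infected), 0 to 15 (RG minus control, uninfected), 0 to 12 (BHB minus control, uninfected), 0 to 0 (BHB minus RG, uninfected, and the interaction) and 269 to 418 (overlap). The number of lists ranged from 0 to 2, 3 to 4, 3 to 4 and 0 to 0 in the 4 main comparisons. Of 322 called gene results, 233 kept their call in every such fit. In 6 of the other settings (RLE normalization, DESeq2, the replicate block, the spline, surrogate variables and without the 4 libraries) 273 kept it throughout, over the 12 other settings 164 did, and 240 when the test against a fold change of 1.5 is set aside. With the compared groups alone, the 6 genes named for infection under control had an edgeR adjusted p of 0.0838 to 0.294, and of the genes named in uninfected libraries SULT2A1 in RG alone passed. Reversed were CXCL8 under BHB (0.17 with surrogate variables, -5.75 to 2.12 with a library left out, the highest without uninfected BHB replicate 2) and RND1 under BHB (-4 to 2.74, the highest without that library). Preset genes that did not pass changed direction in some setting in 9 of 12, 3 of 16, 7 of 15 and 9 of 19 cases in the 4 main comparisons.

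Deviations of same-numbered libraries correlated at 0.133 on average (72 pairs, -0.443 to 0.52, 39 over 0.1) against -0.007 for others. Of 48 libraries, 11 correlated best with their own number, and the count given by chance was not computed. A partial pairing by replicate number therefore stays open. Library number showed a structure, since libraries at most 10 numbers apart correlated at 0.177 on average and those further apart at -0.079, and same-numbered libraries lay 19.4 numbers apart on average. With the replicate block the counts were 561 for infection under control, 19 for BHB minus RG in infected libraries, 34 for RG minus control and 16 for BHB minus control in uninfected libraries and 1 for the interaction.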

Other observations

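The tests of regimen genes in uninfected libraries given here were chosen after the results were seen. Some metabolic genes in lists that did not pass as a whole also differed between regimens in infected liver. The fatty acid oxidation genes ETFDH (0.59 ± 0.12 and 0.54 ± 0.12) and HADHA (0.61 ± 0.14 and 0.62 ± 0.14) and OGDH of the TCA cycle (0.70 ± 0.18 and 0.68 ± 0.18) were higher in RG and in BHB than in control. The thiolase gene ACAT1 of ketone body metabolism (-0.90 ± 0.21 and -1.10 ± 0.21), the desaturase gene SCD (-1.18 ± 0.29 and -1.45 ± 0.29), the glycogen-targeting gene PPP1R3C (-1.70 ± 0.35 and -1.72 ± 0.34) and ACOT12 (-1.35 ± 0.31 and -1.69 ± 0.31) were lower in both. Each of these 7 genes had an edgeR adjusted p of at most 0.0187 in both comparisons and kept its call with any library left out. OGDH did not pass with the compared groups alone (edgeR adjusted p = 0.078 in RG and 0.0635 in BHB), nor SCD in RG without 4 libraries that stood apart (0.0538) or without the 2 infected control libraries among them (0.05). Against a fold change of 1.5, ETFDH, HADHA, OGDH and ACAT1 did not pass in either comparison, nor SCD and ACOT12 in RG. The fatty acid oxidation list had 3 rises of 19 in RG (3 adjusted over the list alone, median 0.22, camera adjusted p = 0.249) and 2 in BHB (2, and 1 fall, median 0.16, 0.524). Lipogenesis had 2 falls of 17 in RG (3, median -0.28, camera adjusted p = 0.54) and 3 in BHB (3, median -0.07, 0.775).

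A hypothesis was that the regimen responses seen in infected liver are present without infection. Of 526 genes called in RG minus control among infected libraries, 497 (94.5%) had the same direction in uninfected libraries, against 67% of all genes, with a median change in the called direction of 1.04 in infected and 0.97 in uninfected libraries. Fry with the called directions gave p = 1.42e-09 in uninfected libraries, a p of a model over all 48 libraries and not an exact test. For BHB minus control, 87.8% of 960 genes (61.5% of all genes) had the same direction, with medians of 0.89 and 0.63 and a fry p of 1.7e-05. These values are consistent with the hypothesis, but both uninfected comparisons rest on the same 2 control libraries, and the difference between infected and uninfected responses, tested as the interaction, gave 0 genes in edgeR (363 at an unadjusted p under 0.05, 2 in DESeq2, 14 in limma-voom).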
